A study of Mus musculus with 8 samples.

How the data were processed

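RNA was measured in 8 soleus muscle samples, 4 from MyoCre control mice and 4 from K15-SKO mice, all aged 2 months. Per the labels' protocols, total RNA was isolated with a column kit and libraries were prepared with the sequencing manufacturer's procedure. The authors deposited 1 table with 24033 genes and a value for each library. The deposited values are taken here to be FPKM (fragments mapped to a gene, divided by its transcript length and by the size of the library), which the authors made with Cufflinks and Cuffdiff per the submitters' processing notes. That unit was inferred, because the header of the table gives only sample names. The submitters' processing notes name STAR, Cufflinks, Cuffdiff and the mm10 genome build without versions, and the values are not whole numbers and do not add up to a common total. The annotation release, the strand setting, any filter and the way the authors scaled the libraries are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and members of families with near-identical copies, such as the haemoglobin genes, are uncertain because reads can match several of them.

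Each library was assigned to its genotype and replicate number through its label. The table holds 0 further columns of values. An exact 0 in this table need not mean that a gene was silent. Ppia, which most cells express, had 0 to 0.29 FPKM over the libraries of both genotypes, and Gapdh had at most 1.11 FPKM in this muscle. A gene with no value in a whole genotype is therefore described as listed at 0, with its value in each library and without a fold change.

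Sequencing depth is not given with FPKM. It was estimated from FPKM times transcript length in single-transcript genes longer than 1 kb. The most common of the lowest such values in a library was assumed to stand for 1 fragment. The estimates were 8790000, 22100000, 8120000 and 10100000 fragments for MyoCre replicates 1 to 4, and 9510000, 9370000, 12900000 and 7910000 for K15-SKO replicates 1 to 4. A gene with 1 kb of transcript and 1 FPKM therefore rested on 7.91 to 22.1 fragments. Spread at that level includes counting error, which is smallest in MyoCre replicate 2. No counts were recovered, so no count model was run.

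Values were tested as log2(FPKM + 0.5) in limma 3.58.1 under R 4.3.3, with moderated statistics, a mean-dependent trend and robust variance estimation. Genes with a mean of at least 1 FPKM over the 8 libraries were tested, which left 12535 genes. The model held the genotype alone. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A log2 fold change on this scale understates the change of genes with low values. Errors of log2 fold changes are moderated standard errors (SE), and FPKM values are means ± SD over 4 mice. The median log2 fold change of all tested genes was -0.12, and median-of-ratios scaling moved it to 0.00. Gene list results are therefore given relative to the median of all genes. Klf15 was also compared by a two-sided exact permutation test of the FPKM values. The count of genes past the threshold was recomputed in all 35 splits of the 8 libraries into 4 and 4.

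Before the data were examined, 32 gene lists covering muscle metabolism, fibre types, stress, hormone response and other cell types were written. Of these, 31 had at least 3 tested members. The list of 26 mitochondrially encoded genes was not tested, because 2 of them were in the table and 0 passed the filter. Lists were compared with all other genes by limma's camera test with a preset correlation between genes of 0.01. The alternatives were camera with an estimated correlation and the rotation test fry, which asks of each list by itself whether its genes move one way. Members were also counted after adjustment over the list alone.

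The genes named in the text were chosen by a rule fixed together with the lists. It takes Klf15; the 12 largest rises and 12 largest falls past the threshold whose libraries do not overlap between the genotypes, filled up to 6 per direction with the smallest unadjusted p where fewer qualify; up to 4 members of each list with the smallest p; and all KLF15-linked genes. The rule only counts predicted genes and pseudogenes, and those named in the text, such as Gm24233, were chosen after their values were seen. The values of 1 gene that the rule takes are not reported here. Other genes past the threshold, further members of a list and reference genes are named where they help to describe a group, and these were chosen after their values were seen.

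The counts of genes past the threshold, the gene lists and the fold changes of Klf15 and of the named genes that stayed in the fit were recomputed under alternatives fixed beforehand: pseudocounts of 1 and 0.1, no filter or a minimum mean of 5, median-of-ratios, upper-quartile or quantile scaling, no robust estimation, library weights, the replicate number as a block, sex as a covariate, and leaving out each library in turn. A 1.5-fold minimum was applied to the counts of genes alone. The exact permutation test was not recomputed, and the splits were recomputed only without the genes listed at 0, with and without median-of-ratios scaling. After the data were seen, fits without the genes listed at 0 in all 4 libraries of a genotype were added, alone and together with some of these settings. Principal components and Pearson correlations of the log2 values described the agreement of the libraries.

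Coordinates and gene types come from GENCODE M21, which uses the mm10 sequence (GRCm38), and not from the deposited table. Of the 24033 gene identifiers, 18786 (78.2%) matched it with their version and 23896 (99.4%) without it, and 96.3% of the latter had the same symbol. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

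The fitting procedure was tested on simulated values for 12376 genes, 4 against 4 libraries, with the spread of these data. It recovered 52% of 100 genes changed by 2-fold and 96% of 100 genes changed by 4-fold, with 5 false calls among 153, and made 0 calls when nothing was changed.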

Results

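The soleus, a hindlimb muscle rich in slow oxidative fibres, was profiled by RNA sequencing in mice aged 2 months. The 4 MyoCre controls carried 1 copy of a Cre recombinase driven from the myogenin gene, which is active in skeletal muscle. The 4 K15-SKO mice carried the same Cre together with floxed alleles of Klf15, so that the gene would be deleted in muscle. KLF15 is a Kruppel-like zinc finger transcription factor known as a regulator of amino acid and lipid metabolism. The comparison asks how the muscle transcriptome differs when this factor is deleted. The deposited FPKM values of the libraries summed to between 519884 and 652275, and the depth estimated from the values was 7910000 to 22100000 fragments per library.

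Klf15 mRNA was lower in K15-SKO muscle and did not disappear. It measured 41.6 ± 12.7 FPKM in MyoCre and 16.2 ± 2.58 FPKM in K15-SKO muscle (SD, n = 4 each), or 38.9% of the control level. The log2 fold change was -1.28 (SE 0.25, limma adjusted p = 0.0315), and -1.16 relative to the median of all genes. The MyoCre libraries held 44.5, 49.8, 49.1 and 22.8 FPKM, and the K15-SKO libraries 15.7, 19.3, 16.7 and 13.1 FPKM, so every K15-SKO library lay below every MyoCre library. A two-sided exact permutation test of the FPKM values (n = 4 each) gave p = 0.0286, the smallest value that 70 assignments allow. The gene (ENSMUSG00000030087.11) lies on chromosome 6 from 90462576 to 90475238 on the plus strand of mm10. Which part of it was floxed is not given in the sources used here, and reads outside the deleted part, or from cells without Cre, are included in these values. The adjusted p passed the threshold in 10 of 28 alternative fits. It was 0.0995 (log2 fold change -1.15) with median-of-ratios scaling and 0.0943 in a fit without the genes listed at 0, and leaving out MyoCre replicate 1, 2 or 3 or K15-SKO replicate 1, 3 or 4 also ended the call, with adjusted p-values of 0.135, 0.0932, 0.218, 0.0937, 0.151 and 0.054.

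Among genes with values in both genotypes, 23 passed adjusted p 0.05, and all 23 were lower in K15-SKO muscle. The largest fall by log2 fold change was that of Acot1, a cytosolic thioesterase that hydrolyses acyl-CoA, from 7.42 ± 1.71 to 1.56 ± 0.85 FPKM (log2 fold change -2.04, SE 0.33, adjusted p = 0.0106). Gstm7, a glutathione S-transferase, fell from 7.98 ± 3.62 to 1.55 ± 0.38 FPKM (log2 fold change -1.98, SE 0.27, adjusted p = 0.00166). Adhfe1, a mitochondrial hydroxyacid-oxoacid transhydrogenase on chromosome 1 (9547948 to 9580673), fell from 14.8 ± 3.65 to 3.47 ± 0.90 FPKM (log2 fold change -1.94, SE 0.23, adjusted p = 0.000328). Selenbp1, a methanethiol oxidase, fell from 22.1 ± 6.94 to 5.98 ± 0.76 FPKM (log2 fold change -1.76, adjusted p = 0.000385), and Cth, which makes cysteine from cystathionine, from 6.56 ± 0.71 to 1.74 ± 0.81 FPKM (log2 fold change -1.73, adjusted p = 0.00189). Gstk1, a glutathione S-transferase of mitochondria and peroxisomes, fell to 37.0% of the control level, Pdp2, a phosphatase that activates pyruvate dehydrogenase, to 37.1%, and Pxmp2, a channel of the peroxisomal membrane, to 42.1%. Abat, the GABA transaminase, fell from 4.03 ± 0.93 to 1.47 ± 0.33 FPKM. Klf15, Bcat2, Ivd, Aldh2, Dhtkd1, Ccbl2, Slc25a29, Ttc38, Zfyve21 and the predicted gene Gm24233 are among the 11 that no longer passed when the same model was fitted without the genes listed at 0. Gm24233 is annotated as a small nucleolar RNA, on chromosome 12 from 59134072 to 59134193.

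The number of lower genes depended on what else was tested. In a fit without the genes listed at 0 in a whole genotype, 12 of the 23 passed: Acot1, Gstm7, Adhfe1, Selenbp1, Cth, Dbt, Gstk1, Pdp2, Bckdhb, Pxmp2, Abat and Isoc2a. That number became 3 (Adhfe1, Selenbp1 and Gstk1) when median-of-ratios scaling was added. It became 0 with quantile normalization added (444 genes at unadjusted p under 0.05) and 0 without K15-SKO replicate 3 (525 genes at unadjusted p under 0.05), a library that stood apart from the rest. With the genes listed at 0 kept, the 23 became 17 (16 lower, 1 higher) without K15-SKO replicate 3, 27 (26 lower, 1 higher) without MyoCre replicate 2, the 1 male library, 6 without MyoCre replicate 3, 11 without MyoCre replicate 1 and 13 without K15-SKO replicate 1. Adhfe1, Selenbp1 and Gstk1 each passed in 26 of 28 alternative fits.

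**Figure D1:**
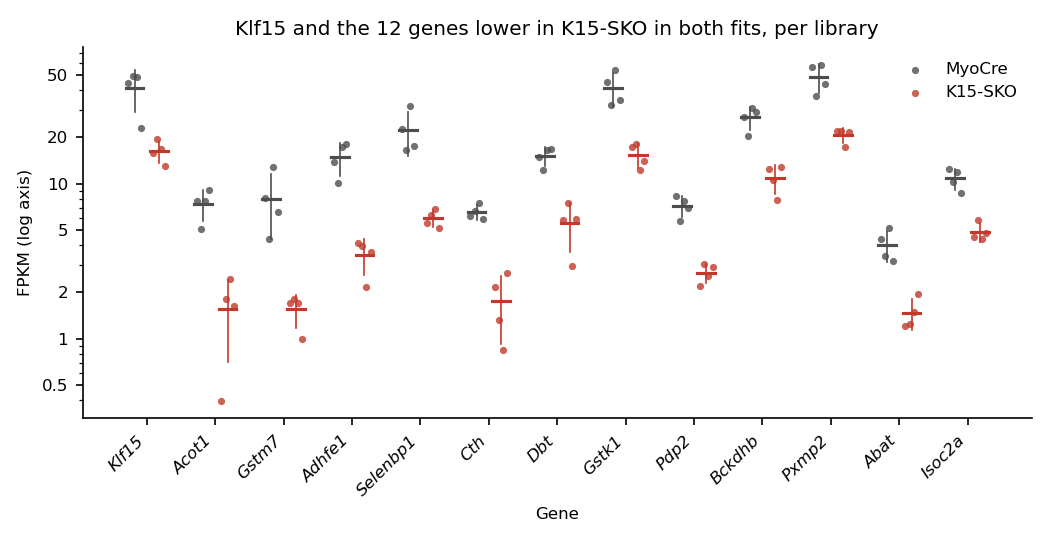
FPKM (log axis) of Klf15 and of the 12 genes that were lower in K15-SKO muscle in the fits with and without the genes listed at 0. Each point is 1 library, horizontal bars are means and vertical lines ± SD (n = 4); for every gene the K15-SKO points lie below the MyoCre points, as for Klf15 with 13.1 to 19.3 FPKM against 22.8 to 49.8 FPKM.

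The clearest group was the catabolism of the branched-chain amino acids leucine, isoleucine and valine. Of its 25 tested members 4 were lower over all genes and 13 were lower when adjusted over the list alone, with none higher in either count. Bcat2, the transaminase of the first step, fell from 19.7 ± 4.28 to 7.77 ± 2.24 FPKM (log2 fold change -1.30, SE 0.23, adjusted p = 0.0173). Bckdhb and Dbt, the E1 beta and E2 subunits of the branched-chain ketoacid dehydrogenase that catalyses the next and committed step, fell from 26.8 ± 4.58 to 10.9 ± 2.29 FPKM (adjusted p = 0.00693) and from 15.1 ± 2.05 to 5.56 ± 1.91 FPKM (adjusted p = 0.0114). Bckdhb lies on chromosome 9 from 83925145 to 84124240. Ivd, the isovaleryl-CoA dehydrogenase of leucine breakdown, fell from 61.4 ± 10.4 to 32.2 ± 3.04 FPKM (adjusted p = 0.0339). Aldh6a1, of valine breakdown, measured 75.3 ± 15.7 FPKM in MyoCre and 37.3 ± 8.63 FPKM in K15-SKO muscle (adjusted p = 0.0831). The kinase Bckdk and the hydratase Auh, with log2 fold changes of 0.01 and 0.06, did not differ detectably. The median of the list lay 0.42 below that of all genes on the log2 scale (camera adjusted p = 7.84e-13; adjusted p = 0.525 with an estimated correlation). Each of the 4 K15-SKO libraries had a lower mean score for the list, from -0.65 to -0.10, than each MyoCre library, from 0.17 to 0.46. These scores were not taken relative to all genes. K15-SKO replicate 3, with the score of -0.65, also had the lowest median-of-ratios factor, 0.80 against 0.97 to 1.16 in the other libraries. Bcat2 and Ivd did not pass in the fit without the genes listed at 0 (adjusted p = 0.0629 and 0.0986). Markers of fat cells, which also break down these amino acids, had a median 0.14 below that of all genes (adjusted p = 0.252).

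**Figure D2:**
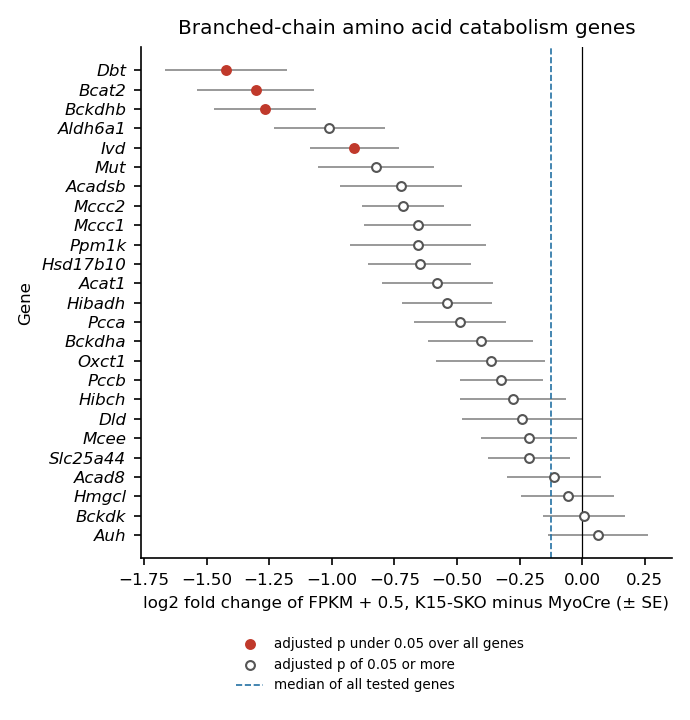
Log2 fold change of FPKM + 0.5, K15-SKO minus MyoCre, for the 25 tested genes of branched-chain amino acid catabolism, with horizontal lines for ± SE and 4 libraries per genotype. Filled points (Dbt, Bcat2, Bckdhb and Ivd) passed adjusted p 0.05 over all genes, and the dashed line is the median of all tested genes, -0.12.

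As lists, amino acid genes outside that pathway and lipid genes had medians closer to that of all genes. Of 16 tested KLF15-linked genes, known from earlier work on this factor, Klf15 and Bcat2 were lower over all genes and 6 were lower when adjusted over the list alone (median 0.18 below that of all genes, adjusted p = 1.38e-06; adjusted p = 0.525 with an estimated correlation). This list holds the deleted gene itself and could not be tested without Klf15 and shared members. A median as large arose in 8 of 35 splits. Prodh, the first enzyme of proline breakdown, measured 6.16 ± 2.53 and 2.29 ± 1.24 FPKM in MyoCre and K15-SKO muscle (adjusted p = 0.469), and the alanine transaminase Gpt 18.8 ± 3.96 and 9.83 ± 2.59 FPKM (adjusted p = 0.188). Aldh4a1 of proline breakdown had a log2 fold change of -0.78 (adjusted p = 0.140) and Hibadh of valine breakdown one of -0.54 (adjusted p = 0.694). The remaining members also missed the threshold over all genes, with log2 fold changes given in brackets: the glucose transporter Slc2a4 (-0.23), the fatty acid carriers Slc27a1 (-0.34), Fabp3 (-0.19) and Slc25a20 (-0.36), and Cpt1b (-0.16), Cpt2 (-0.21) and Acadm (-0.27) of mitochondrial fatty acid oxidation. The atrophy ubiquitin ligases Fbxo32 (-0.09) and Trim63 (-0.05) and the nuclear receptor Ppard (-0.01) had signs that turned under median-of-ratios scaling. In other amino acid metabolism 0 of 22 members passed over all genes and 4 were lower when adjusted over the list alone, among them the ornithine aminotransferase Oat with 61.5 ± 11.2 and 35.5 ± 4.20 FPKM (median 0.15 below that of all genes, adjusted p = 0.000250; adjusted p = 0.525 with an estimated correlation, and 0.091 without the genes that occur in another list).

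In fatty acid beta-oxidation 1 of 29 members was lower over all genes, and 2 were lower when adjusted over the list alone. All 29 fold changes were negative and 26 lay below the median of all genes, with the list's median 0.20 below it (adjusted p = 1.10e-06; adjusted p = 0.525 with an estimated correlation). The enoyl-CoA hydratase Echs1 measured 109.1 ± 17.9 and 63.0 ± 14.3 FPKM (adjusted p = 0.207), and Acaa2 and Etfa had log2 fold changes of -0.49 and -0.51. Among 21 PPAR target genes Acot1 was lower over all genes, and 2 were lower when adjusted over the list alone (median 0.21 below that of all genes, adjusted p = 2.42e-06; adjusted p = 0.525 with an estimated correlation). The solute carrier Slc25a34 just missed the threshold with 32.7 ± 5.41 and 13.8 ± 6.06 FPKM (adjusted p = 0.0534), and lipoprotein lipase, Lpl, measured 485.1 ± 102.7 and 272.3 ± 112.2 FPKM (adjusted p = 0.825). Other well-known PPAR targets also missed the threshold, such as Pdk4, Ucp3 and Angptl4 with log2 fold changes of -0.36, -0.29 and -0.24.

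**Figure D3:**
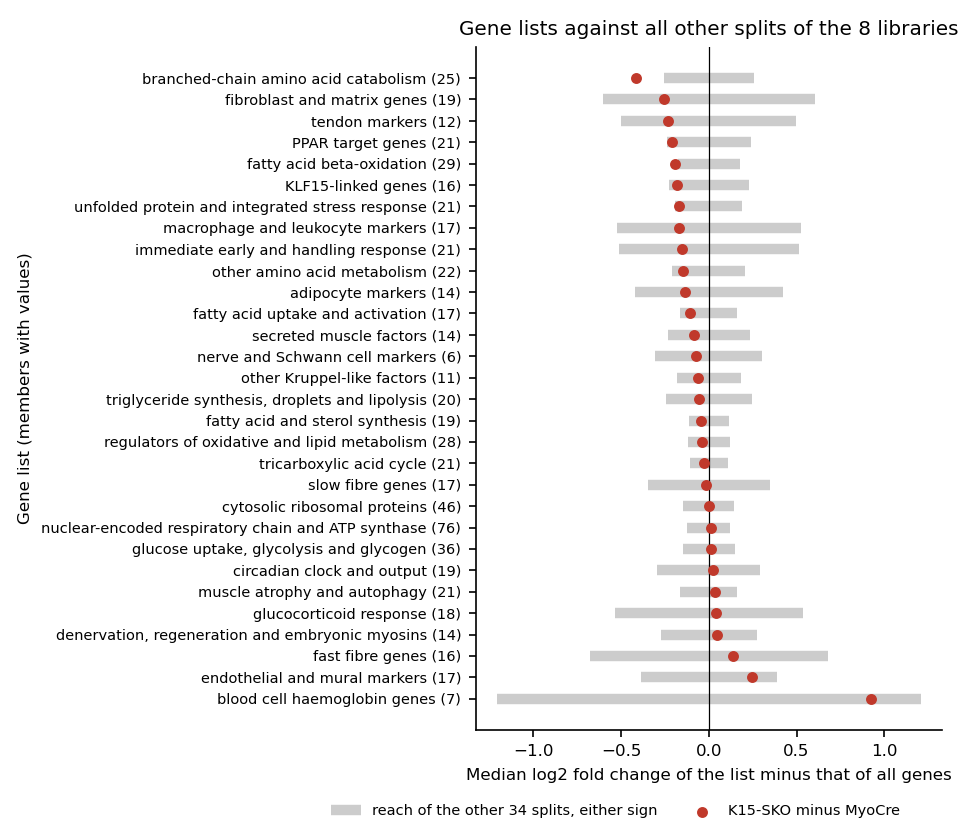
Median log2 fold change (K15-SKO minus MyoCre) of 30 gene lists relative to the median of all genes, without the genes listed at 0; numbers in brackets are the members with values. Red points are the comparison of the genotypes, and grey bars reach to the largest value, in either sign, over the other 34 splits of the 8 libraries; the branched-chain list (-0.42 against 0.25) and the beta-oxidation list (-0.20 against 0.18) lie outside their bars.

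Of the contractile and respiratory lists the fast fibre list alone passed the camera test. It did so upward, its median 0.14 above that of all genes (adjusted p = 1.38e-06, or 0.000222 without its member listed at 0, Myh2; adjusted p = 0.525 with an estimated correlation). A median as large arose in 22 of 35 splits of the libraries, and none of its members with values in both genotypes was higher by either adjustment. The slow fibre list had a median 0.02 below that of all genes (adjusted p = 0.990), with Myh7, the slow myosin, at 1609 ± 698.3 and 1385 ± 598.1 FPKM. Among fast fibre genes the IIb myosin Myh4 ranged from 3.48 to 66.7 FPKM in MyoCre and from 11.02 to 285.0 FPKM in K15-SKO muscle (adjusted p = 0.957), Actn3 measured 39.5 ± 6.91 and 71.5 ± 42.2 FPKM, and Myh2 was listed at 0 in MyoCre. The nuclear-encoded respiratory chain (median 0.01 above all genes, adjusted p = 0.783), the tricarboxylic acid cycle (0.03 below, adjusted p = 0.180), glucose uptake, glycolysis and glycogen (0.01 above, adjusted p = 0.953), and regulators of oxidative metabolism (0.04 below, adjusted p = 0.598) did not pass. The slow fibre test pointed up against its median, and the glycolysis test down against its median. The atrophy and autophagy list passed upward (median 0.06 above, adjusted p = 0.000421; adjusted p = 0.525 with an estimated correlation), and without its members listed at 0, Map1lc3b and Fbxo31, it did not (adjusted p = 0.465).

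No gene with values in both genotypes was higher past the threshold in the model with the genotype alone and all 8 libraries. The smallest unadjusted p-values in that direction belonged to the cell adhesion gene Pcdh1, with 3.53 ± 0.76 and 6.19 ± 0.43 FPKM (log2 fold change 0.75, adjusted p = 0.141), the folate enzymes Aldh1l1 (0.84) and Mthfd2 (0.62), the calcium channel subunit Cacng1 (0.68), the histone gene Hist1h3i (0.75) and the glycogen-binding Stbd1 (0.63). All of these missed the threshold.

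Lists of markers of other cell types and of handling passed the test as well. Endothelial and mural markers had a median 0.24 above that of all genes (adjusted p = 0.000436; adjusted p = 0.525 with an estimated correlation), with the junction gene Cdh5 at 23.1 ± 4.03 and 30.9 ± 1.23 FPKM and Tek at a log2 fold change of -0.10. Haemoglobin and other erythroid genes lay 0.93 above (adjusted p = 1.10e-06; adjusted p = 0.525 with an estimated correlation), and 0.20 above without K15-SKO replicate 3. Fibroblast and matrix genes lay 0.26 below (adjusted p = 0.00288; adjusted p = 0.783 with an estimated correlation) and tendon markers 0.23 below (adjusted p = 0.00276; adjusted p = 0.603 with an estimated correlation). Col1a2 measured 176.4 ± 60.0 and 116.0 ± 27.5 FPKM, and the tendon proteoglycan gene Kera 13.2 ± 3.29 and 6.23 ± 2.77 FPKM. Immediate early genes lay 0.15 below (adjusted p = 0.0120; adjusted p = 0.525 with an estimated correlation), and the heat shock gene Hspa1a just missed the threshold with 7.59 ± 1.74 and 3.56 ± 0.78 FPKM (adjusted p = 0.0568). No member of these 5 lists passed over all genes. Adjusted over the list alone, 2 tendon and 4 immediate early members were lower and none of the other 3 lists' members passed. Over all lists 12 passed, 8 downward and 4 upward, and 11 of 35 splits of the libraries gave as many. With library weights 12 passed downward and 2 upward, and the endothelial and haemoglobin lists missed the threshold (adjusted p = 0.0809 and 0.116). Without K15-SKO replicate 3, 12 passed downward and 3 upward, and the endothelial list missed it (adjusted p = 0.134).

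The libraries did not separate by genotype as a whole. The median Pearson correlation of log2 values was 0.940 within a genotype and 0.941 between genotypes, and the first 2 principal components held 26.5% and 22.1% of the variance. K15-SKO replicate 3 stood at the end of the first component, with 14.1% of its FPKM sum in the small nuclear RNA Rn7sk against 8.67% to 10.5% in the other libraries. MyoCre replicate 2 was the deepest library, with an estimated 22100000 fragments, and the only male: its Y-linked genes averaged 16.2 FPKM and its Xist 0.0103 FPKM, against 0 and at least 20.998 FPKM in the other 7.

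A further 46 genes passed the threshold as higher in K15-SKO muscle, and all 46 were listed at 0 in all 4 MyoCre libraries. They include Acta1, the skeletal muscle actin, which had 12825, 14415, 16091 and 10382 FPKM in the K15-SKO libraries, and Cox4i1, a subunit of cytochrome c oxidase, which had 1018, 1128, 987.2 and 783.1 FPKM. The fast IIa myosin Myh2 had 1514, 2095, 1281 and 738.1 FPKM in the K15-SKO libraries. The rule for named genes also takes Map1lc3b, Tcf25, Trappc2l, Chmp1a, Rpl13, Fbxo31, Spg7, Rhou and Snai3, all listed at 0 in MyoCre as well. Of the 46 genes 43 overlap 1 stretch of chromosome 8, from 119910841 to 124345722, which is spanned by a single gene model, Gm20388, of 4434882 bases. This stretch overlaps 79 genes with a value in K15-SKO muscle, and all 79 were listed at 0 in every MyoCre library. None of the 10 nearest tested genes outside it was at 0 in all MyoCre libraries. The remaining 3 genes were Myh2 and the predicted genes Gm29216 and Gm28437. Acta1 lies within the stretch, from 123891769 to 123894751. No fold change is given for these genes, and levels in MyoCre muscle cannot be read from the table.

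**Figure D4:**
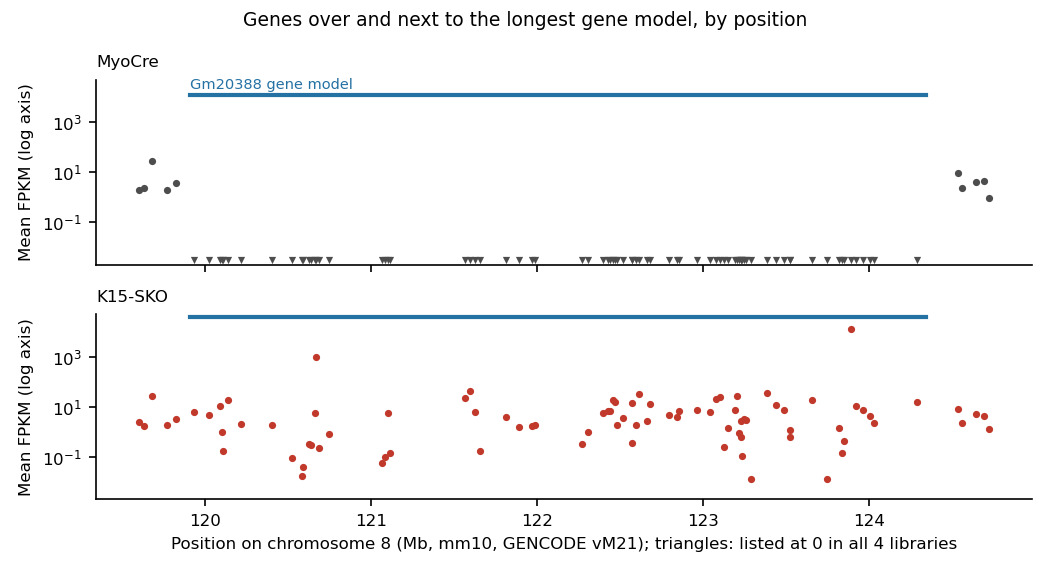
Mean FPKM over 4 libraries (log axis) of genes on chromosome 8 by the midpoint of their position in Mb, in MyoCre (top) and K15-SKO muscle (bottom); triangles stand for genes listed at 0 in all 4 libraries of the genotype, and the blue line is the Gm20388 gene model. All 79 genes overlapping the model are listed at 0 in MyoCre, and the 10 nearest tested genes beside it have values.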

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

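The tests of explanations in this part were chosen after the results were seen; only the way of finding values far from the rest of their group was set beforehand. It compares the gap between the most extreme of 4 libraries and its nearest neighbour with the range of the group. Of 332 groups of 4 values, 15 held such a value, where chance at 1 in 20 gives 16.6; 6 of the 15 were in K15-SKO replicate 3.

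The 79 genes of 1 stretch of chromosome 8, Acta1 and Cox4i1 among them, were listed at 0 in all 4 MyoCre libraries and had values in K15-SKO muscle. A candidate explanation is the authors' processing: overlapping gene models, joined by the very long Gm20388, may have been handled as 1 locus whose estimate failed in the MyoCre group. It predicts zeros in every overlapping gene and none beside them, and 79 of 79 overlapping genes and 0 of 10 flanking genes were at 0. That prediction was written after the zeros had been seen. A loss of the transcripts of this stretch from every cell would give the same zeros, so the result does not tell these explanations apart. A loss only in cells with active Cre is argued against. The K15-SKO mice carried the same Cre and had values. Cells of other types were in the MyoCre samples, with means of 23.1 FPKM of Cdh5, 6.33 FPKM of Csf1r and 176.4 FPKM of Col1a2. Even so, all 79 genes, the ribosomal protein gene Rpl13 among them, were at exactly 0. A loss in every cell of the MyoCre animals was not tested and stays open. Zeros of this kind were not limited to the stretch: Myh2, on chromosome 11, was also listed at 0 in all 4 MyoCre libraries, with a mean of 1407 FPKM in K15-SKO muscle.

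Of 25 genes of branched-chain amino acid catabolism 4 were lower in K15-SKO muscle over all genes, and the list passed the camera test downward (adjusted p = 7.84e-13; adjusted p = 0.525 with an estimated correlation, and 0.429 over the 35 splits). Fewer fat cells in those samples could not be judged from levels. The 13 adipocyte markers without Fabp4 summed to 112.0 FPKM in MyoCre and 88.9 FPKM in K15-SKO muscle (-23.1 FPKM). The 25 branched-chain genes summed to 1239.9 and 912.9 FPKM (-327.0 FPKM). The whole marker sum in MyoCre was smaller than that difference, so its fall could not have matched it, and this explanation stays open. Fabp4, which endothelial cells also express, was left out after the sum with it had been seen to differ by 24.4 FPKM in the other direction. The distant library K15-SKO replicate 3 as the only source is argued against. Without that library and with median-of-ratios scaling the list still lay at -0.38 relative to all genes, where no other grouping of the 7 libraries exceeded 0.26 in size. Scaling was hardly tested by this, because a factor per library nearly cancels in a median taken relative to all genes. Over all 8 libraries that median was -0.40 with the scaling and -0.42 without it. The loss of KLF15 in muscle remains open as a hypothesis and was not tested against other differences between the mice.

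The haemoglobin list passed the camera test upward in K15-SKO muscle (adjusted p = 1.10e-06; adjusted p = 0.525 with an estimated correlation), with none of its members past the threshold and a median as large in 7 of 35 splits. K15-SKO replicate 3 had 1265 FPKM of Hbb-bs and 220.4 FPKM of Hba-a2, against at most 365.3 and 58.6 FPKM in the other K15-SKO libraries. Blood left in that sample is a candidate explanation: the list's median relative to all genes was 0.93 with it and 0.20 without it. Whether the other 3 K15-SKO samples also differ from the 4 MyoCre samples is open (exact permutation p = 0.457, two-sided). No biological explanation was tested.

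The other distant values are these. In K15-SKO replicate 3, Pxmp2 measured 17.2 FPKM against 21.5 to 22.0 in the other 3 libraries of the genotype. In the same library the tricarboxylic acid cycle gene Fh1 had 71.6 FPKM against at least 104.9, Igf2 had 16.9 FPKM against at most 6.49, and Rn7sk took 14.1% of the FPKM sum against at most 9.42%. Gstm7 had 0.989 FPKM in K15-SKO replicate 4 against 1.69 to 1.81, and the immediate early score of that library was -0.36 against -0.10 to -0.05. K15-SKO replicate 1 had 28.8 FPKM of the clock gene Bhlhe40 against at most 20.5, and 29.1 FPKM of Cdh5 against 31.3 to 31.8. MyoCre replicate 3 had 40.8 FPKM of Slc25a34 against 29.3 to 30.7, and 78.3 FPKM of Oat against 55.2 to 56.5. MyoCre replicate 2 had 5.15 FPKM of the matrix gene Tnc against 2.80 to 3.01, and an estimated 22100000 fragments against 8120000 to 10100000. MyoCre replicate 4 had 1.10 FPKM of Rps16 against 1.88 to 1.98.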

How the results depend on the processing

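The fits without the genes listed at 0, and the block combined with scaling, were chosen after the data were seen; all other settings here were fixed beforehand. The cause was not tested for any change below, except where fewer genes or libraries entered the fit.

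The 23 genes with values in both genotypes became 15 without the low-value filter, 15 with median-of-ratios scaling (14 of them among the 23), 14 with upper-quartile scaling, 14 with quantile normalization and 15 without robust estimation. Library weights gave 111, of which 101 were lower and 10 higher, and all 23 were included. These weights were uneven, so that fit leaned on replicate 1 of each genotype. They ran from 0.20 (replicate 3) to 4.69 (replicate 1) in K15-SKO and from 0.51 (replicate 4) to 2.29 (replicate 1) in MyoCre. Leaving out 1 library gave 6 to 27, with up to 2 of them higher. Without the genes listed at 0 the number was 12, and then 3 with median-of-ratios scaling, 0 with quantile normalization, 91 with library weights, 15 with sex as a covariate, 15 without the male library and 0 without K15-SKO replicate 3. Both counts of 0 are limma counts, with 444 and 525 genes at unadjusted p under 0.05. All 69 genes past the threshold became 39 with a minimum mean of 5, 157 with library weights and 53 to 74 with 1 library left out. Of these, 46 of 69 were higher, against 56 of 157 with library weights and 66 of 84 without the filter.

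Klf15 kept its direction in every setting run. Its log2 fold change missed the threshold at -1.28 without the low-value filter, without robust estimation and without the genes listed at 0; at -1.15 with median-of-ratios, upper-quartile or quantile scaling; and at -1.18 with sex as a covariate. Without the genes listed at 0 it missed at -1.15 with median-of-ratios scaling, -1.14 with quantile normalization, -1.18 with sex or without the male library, and -1.30 without K15-SKO replicate 3. Leaving out 1 library gave -1.55 to -1.18. Adjusted p ranged from 0.000195 with library weights, a fit that leaned on replicate 1 of each genotype, to 0.323.

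The 12 gene lists became 10 without Klf15 and shared members (the KLF15-linked list could then not be tested, and other amino acid metabolism missed at 0.091), 0 with an estimated correlation (0 at unadjusted p under 0.05) and 0 with fry (9 at unadjusted p under 0.05), and 9 to 15 with 1 library left out. The 8 downward and 4 upward became 12 and 2 with library weights and 12 and 3 without K15-SKO replicate 3. 14 lists that did not pass changed the sign of their relative median in 47 settings, as did 1 that passed, muscle atrophy and autophagy.

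Of 2568 values of 130 named genes under the alternatives, 2472 kept direction and side of the threshold, 45 no longer passed, 28 newly passed and 23 changed sign, all in 6 genes that did not pass. With library weights Nfe2l2 was at 0.00674, Myh8 at -0.023 and Fbxo32 at 0.0051. Fbxo32, Ppard and Trim63 were at 0.047, 0.11 and 0.091 with median-of-ratios, 0.040, 0.11 and 0.085 with upper-quartile and 0.029, 0.097 and 0.054 with quantile scaling. With sex as a covariate Xist was at -0.32 and Trim63 at 0.30. Leaving out 1 library gave -0.32 to 1.87 for Xist, -0.24 to 0.20 for Fbxo32, -0.15 to 0.11 for Ppard and -0.42 to 0.30 for Trim63.

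The replicate numbers were not taken to pair the samples. Deviations from the genotype means correlated at 0.15, 0.34, 0.01 and 0.34 for equal numbers. With the replicate block 32 genes with values were lower, 19 of them among the 23, and 78 passed in all. After median-of-ratios scaling the block gave 27 (25 lower and 2 higher) and 73. Without the genes listed at 0 it gave 24 genes, all lower and 17 of them among the 23. Klf15 passed in these 3 fits (adjusted p = 0.00534, 0.0133 and 0.0291). K15-SKO replicate 3 correlated best with MyoCre replicate 2, and MyoCre replicate 3 with K15-SKO replicate 1; the other libraries correlated best with their own number.

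A count model was planned only for counts and was not run, since the table holds none. With the spread of these data 52% of simulated 2-fold changes were recovered, so smaller differences were not detectable for many genes. The simulation drew independent noise of equal spread for every library and set no sequencing depth.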

Other observations

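The gene lists and the count of all genes past the threshold over the splits were planned. The other tests over splits (the 23, 12 and 3 genes, the number of lists and the list medians) and the tests of the 2 gene classes below were chosen after the data were seen.

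The lists not described above did not pass. Bdnf, a neurotrophin that muscle also makes, measured 2.67 ± 1.30 FPKM in MyoCre and 0.574 ± 0.30 FPKM in K15-SKO muscle (SD, n = 4 each; limma adjusted p = 0.0568), and the secreted factor gene Metrnl 13.7 ± 4.12 and 8.07 ± 0.91 FPKM (adjusted p = 0.519). Secreted muscle factors as a list lay 0.09 below all genes (adjusted p = 0.511), with 2 lower when adjusted over the list alone. The unfolded protein and integrated stress response list lay 0.17 below (adjusted p = 0.166), with the chaperone genes Hspe1 and Hspa5 at log2 fold changes of -0.69 and -0.63 and Mthfd2 at 0.62. Among other Kruppel-like factors (0.06 below, adjusted p = 0.297) Klf4, Klf10, Klf12 and Klf9 had log2 fold changes of -0.45, -0.56, -0.37 and -0.32. Clock genes (0.02 above, adjusted p = 0.990; mean and test pointed down) included Bhlhe40 at -0.52 and Arntl at -0.59. Glucocorticoid response genes lay 0.04 above (adjusted p = 0.701), with Dusp1 at -0.39 and Errfi1 at -0.41.

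Lipid lists outside oxidation did not pass: fatty acid uptake and activation lay 0.11 below all genes (adjusted p = 0.596), triglyceride synthesis, droplets and lipolysis 0.06 below (adjusted p = 0.148), and fatty acid and sterol synthesis 0.04 below (adjusted p = 0.777; its camera test and mean pointed upward, with Mvd listed at 0 in MyoCre). Plin5 and Dgat2, genes of lipid droplets and triglyceride synthesis, had log2 fold changes of -0.55 and -0.48. Among other tissue markers, macrophage and leukocyte genes lay 0.17 below (adjusted p = 0.13), nerve and Schwann cell genes 0.08 below (adjusted p = 0.596), and denervation, regeneration and embryonic myosin genes 0.04 above (adjusted p = 0.183), with the acetylcholine receptor gene Chrnd at 0.49 and Myod1 at -0.56. Cytosolic ribosomal protein genes lay 0.00 above (adjusted p = 0.996). The sex-linked list (adjusted p = 0.893) reflected the 1 male library. Aldh1l1, among the genes with the smallest p-values upward (adjusted p = 0.421), lies beside Klf15 on chromosome 6, from 90486427 to 90600203.

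Chance was examined over all 35 splits of the 8 libraries. For the 69 genes past the threshold 1 split, the real one, gave as many and the highest other gave 3, but 46 of the 69 are listed at 0 in a whole genotype, which fixes that outcome, so it says nothing about chance. For the 23 with values 1 split, the real one, gave as many and the highest other gave 3, but the genes listed at 0 were in that fit and eased the adjustment in the real split, so this says nothing about chance either. For the 12 of the fit without those genes 1 split, the real one, gave as many and the highest other gave 3. That is the smallest share that 35 splits allow, and the fit was chosen after the data were seen. Chance is therefore not excluded for that count, though no other split came near it. For the 3 genes left with median-of-ratios scaling as well, 2 of 35 splits gave as many and the highest other gave 3, so chance cannot be excluded. The 12 gene lists were equalled or exceeded in 11 of 35 splits, the highest other with 13, so chance cannot be excluded for the number of lists. By the size of their median, 2 of 30 lists exceeded all other splits: branched-chain catabolism (-0.42 against 0.25) and beta-oxidation (-0.20 against 0.18), each at the smallest possible p of 0.0286 (0.429 adjusted over 30 lists).

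Whether some lower genes stand for whole classes was asked of the other members of each class. The pairs themselves were picked as large falls, so a class median above theirs decides nothing. Cth and Selenbp1 handle sulfur compounds, and the 18 sulfur amino acid genes had a median of -0.10 relative to all genes (SD 0.61 over the list), against -1.62 for that pair. Without the pair 16 genes had a median of -0.087, with 11 below all genes. A median as large arose in 14 of 35 splits, so a lower class was neither shown nor excluded. Gstm7 and Gstk1 are glutathione S-transferases, and the 16 members of that class had a median of -0.075 (SD 0.62), against -1.56 for that pair. Without the pair 14 genes had a median of -0.0002, with 7 below all genes, and 35 of 35 splits gave one as large. No fall of these other members was seen.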
